A study of Mus musculus with 20 samples.

How the data were processed

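CpG methylation was measured by ERRBS in 20 libraries of sorted mouse promyelocytes. The labels give the genotype (PML-RARα or wild type), the sorted fraction (CD34 positive or negative), the FVB/n background, the flowcell and the lane of each library. The 4 groups of genotype and fraction held 5 libraries each and were taken from the labels alone. According to the submitters' processing notes the authors used CASAVA 1.8.2 and Bismark and the mm9 genome. The deposited values are the count of reads that cover each CpG cytosine of each strand and, per the file headers, the percent of those reads that carry C and the percent that carry T. No cytosine with fewer than 10 reads was listed, and replicates were not pooled. The number of methylated reads at a cytosine was computed as coverage times percent C and rounded, and lay on a whole number at 100% of cytosines, within what rounding of the percent to 2 decimals allows. This tolerance grows with coverage and is below 0.01 reads at a coverage of 150. Total coverage per library, summed over cytosines, ranged from 83631324 to 362881291. A read over several cytosines counts once for each in this sum and in the sums over regions. The reads carry no molecular identifiers, so intervals given for shares of reads cover counting error only.

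Cytosines on chromosomes 1 to 19 with at least 10 reads in all 20 libraries were kept, 1150978 in number. Their methylated and unmethylated reads were summed over fixed windows of 1000 bp with at least 3 such cytosines, which gave 84524 regions. Windows held 90.8% of the kept cytosines. No pair of libraries of a group was a duplicate of another, with a chi-square per region between 4.34 and 27.8.

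Each region was fitted with a quasi-binomial logistic model with 1 term per group. The overdispersion was the Pearson chi-square over 16 residual degrees of freedom, shared by the 4 groups. It was moderated over regions as in limma's squeezeVar (3.07 prior degrees of freedom) and kept at 1 or above, with a median of 9.50. Groups were compared by an F test of the deviance, two-sided, with Benjamini-Hochberg adjustment over regions. A region was called at an adjusted p below 0.05 with a difference of at least 10 percentage points between group means. The comparisons were PML-RARα against WT in each fraction, CD34− against CD34+ in each genotype, and the interaction of both. Mean methylation and region classes were compared by exact permutation of the 10 libraries, two-sided, with adjustment over 4 comparisons and over 24 tests of classes. The groups, tests, thresholds, region classes, naming rule and alternatives were fixed before the data were examined, apart from those named as later in the closing section and the 28 tests of values per library and Fisher's exact test of shared regions, which were added after the scatter of the libraries and the first counts of called regions had been seen.

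Per comparison the regions named were those with the 10 largest increases and 10 largest decreases among called regions, or all where fewer were called, and the 3 smallest p-values in each direction where none was called. For this naming, called regions within 1 kb of each other counted as 1, while the counts of called regions are of single windows. The 20 named regions of the WT maturation comparison and the 19 of the PML-RARα one are given in part. Regions are named by position only. The gene table used was built on GRCm38, while the largest position on chromosome 1 in the files, 197193419, lies beyond the last gene end of that build. Gene lists, promoters, exons and introns were therefore not analysed here.

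The test was checked on simulated beta-binomial counts with the coverage and overdispersion of the real regions. In each comparison 200 regions received a difference of 10 points, 200 others one of 20 points and 200 others one of 40 points. All were set as lower levels in PML-RARα or CD34− libraries, at regions of intermediate to high mean methylation. The rates of recovery therefore do not cover gains or regions of low methylation. Between 13.5% and 19.5% of the differences of 10 points were called, between 69.5% and 73.5% of those of 20 points, and between 95.5% and 98.5% of those of 40 points. False calls made up between 0 and 5.75% of all calls, the highest share in the PML-RARα maturation comparison. Of the unchanged regions, 7.34% had an unadjusted p below 0.05 in that comparison and 2.96% in the WT maturation comparison. Between genotypes the share was 4.95% in CD34+ and 5.46% in CD34− cells. In simulated data the test was thus lenient for PML-RARα maturation and strict for WT maturation. With 10 changed regions of each size, in 20 runs per comparison that were added after the results were seen, between 5.5% and 9.5%, between 47.0% and 50.5% and between 86.5% and 92.0% were called, and false calls made up between 0 and 7.92% of all calls, again highest in the PML-RARα maturation comparison. The moderation was checked against limma, with a largest relative difference of 4.39e-12.

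The alternatives were a coverage minimum of 20, coverage in 4 of 5 libraries per group, windows of 100 bp, single cytosines, a cap on the highest coverage, chromosome X added, libraries thinned to equal coverage, a minimum difference of 25 points or none, only the 2 compared groups in the fit, flowcell as a factor, a replicate block from the number after # in the titles, a replicate block from consecutive title numbers, limma on log2 ratios, an edgeR quasi-likelihood fit, and each library left out in turn. A fit without the 5 libraries of high scatter and a test of the held-out changes by consecutive title numbers were added. Software was Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, matplotlib 3.10.9, R 4.3.3, limma 3.58.1 and edgeR 4.0.16.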

Results

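DNA methylation was measured in promyelocytes, the granulocyte precursors in which PML-RARα acts, sorted from mice of the FVB/n background. Enhanced reduced representation bisulfite sequencing (ERRBS) reads CpG-rich restriction fragments after bisulfite conversion, so that a methylated cytosine is read as C and an unmethylated one as T. The 20 libraries fell into 4 groups of 5: wild-type (WT) control and PML-RARα transgenic mice, each with early promyelocytes that carry CD34 on their surface (CD34+) and late promyelocytes that do not (CD34−). The labels do not state whether the 5 libraries of a group came from separate mice. Total coverage, summed over cytosines, ranged from 83631324 to 362881291 per library. Each library listed between 1718859 and 2213704 CpG cytosines, with a median coverage of 32 to 150 reads. In all 20 libraries, 1150978 autosomal cytosines were covered by at least 10 reads. They filled 84524 regions, fixed 1 kb windows of the mm9 genome with at least 3 such cytosines and a median of 5. A region's methylation level was the percent of its reads that were methylated.

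The scatter of a library was taken as the median distance of its regions of intermediate methylation from the median of the other 4 libraries of its group. It lay between 6.31 and 8.30 percentage points in 5 libraries and between 3.39 and 5.87 in the others. The 5 libraries were WT CD34+ replicate 1, PML-RARα CD34+ replicates 5 and 11, and PML-RARα CD34− replicates 6 and 12. The libraries were sequenced on 4 flowcells, lettered A to D here, with 7, 7, 1 and 5 libraries. WT libraries of both fractions lay on A, B and D. Of the PML-RARα libraries, A held CD34− ones only, C (replicate 19 alone) and D held CD34+ ones only, and B held both fractions.

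The study's design asks first how promyelocytes of PML-RARα mice differ from those of control mice. In CD34+ cells no region passed both an adjusted p below 0.05 and a difference of at least 10 percentage points. The region with the smallest p was on chromosome 3, positions 122135001 to 122136000, where methylation was 53.3% ± 4.81 in PML-RARα and 77.1% ± 6.34 in WT cells (SD, n = 5 each; adjusted p = 0.142). On chromosome 13, positions 44629001 to 44630000, the levels were 27.2% ± 10.7 and 68.0% ± 5.85 (SD, n = 5 each; adjusted p = 0.388). On chromosome 12, positions 77568001 to 77569000, they were 1.48% ± 2.39 and 11.1% ± 3.36 (adjusted p = 0.527). Of regions with a higher level in PML-RARα cells, the smallest p-values belonged to chromosome 17, positions 45979001 to 45980000 (66.6% ± 4.49 against 55.1% ± 2.39), chromosome 12, positions 36396001 to 36397000 (46.2% ± 7.93 against 27.0% ± 8.22), and chromosome 9, positions 61481001 to 61482000 (94.7% ± 3.01 against 80.9% ± 10.1), with adjusted p of 0.534, 0.594 and 0.600. At the last of these, PML-RARα replicate 11 stood at 100%.

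The quasi-binomial test gave 3705 regions with an unadjusted p below 0.05 in CD34+ cells, 4.38% of those tested, and 0 called regions. Limma and edgeR called 0 as well, with 3739 and 2454 regions at an unadjusted p below 0.05. A difference of at least 10 points was measured at 2069 regions, and in simulated data with 10 changed regions of each size the test recovered 5.5% of true differences of 10 points, 48.5% of 20 points and 89.0% of 40 points. With 200 changed regions of each size it recovered 16.0%, 72.5% and 96.5%. Some settings called between 1 and 4 regions, each lower in PML-RARα cells. The chromosome 3 region was called with 4 of 5 libraries per group required, after thinning to equal coverage, and without the 5 libraries of high scatter (adjusted p of 0.0418, 0.0273 and 0.0216). Its adjusted p ranged up to 1.00 over all settings. The chromosome 13 region was called with the first and the last of these settings, and its cytosine at position 44629859 was the only one called singly. The other regions, named after their values were seen, were on chromosome 1, positions 74195001 to 74196000, and chromosome 7, positions 29623001 to 29624000 (4 of 5 libraries), and on chromosome 7, positions 151883001 to 151884000 (thinned).

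In CD34− cells no region was called between the genotypes. The regions with the smallest p and a lower level in PML-RARα cells were on chromosome 2, positions 33831001 to 33832000 (75.6% ± 4.00 against 90.7% ± 3.36), chromosome 17, positions 35401001 to 35402000 (40.6% ± 8.60 against 57.8% ± 4.79), and chromosome 11, positions 52308001 to 52309000 (76.1% ± 5.86 against 90.9% ± 4.47). Those with a higher level were on chromosome 16, positions 84546001 to 84547000 (97.8% ± 0.757 against 92.7% ± 1.45), chromosome 6, positions 87930001 to 87931000 (0.843% ± 0.342 against 0.0983% ± 0.0682), and chromosome 19, positions 12076001 to 12077000 (4.74% ± 4.66 against 0% in each WT library). All values are means ± SD of 5 libraries, and the adjusted p was 0.201 for all 6. The chromosome 13 region named in CD34+ cells stood at 6.53% ± 7.45 in PML-RARα and 35.2% ± 8.19 in WT CD34− cells, and was called with 4 of 5 libraries per group required (adjusted p = 0.0286).

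The quasi-binomial test gave 6802 regions with an unadjusted p below 0.05 in CD34− cells, 8.05% of those tested, and 0 called regions. Limma called 1 and edgeR 0, with 3873 and 2836 regions at an unadjusted p below 0.05. The limma region, on chromosome 4, positions 43436001 to 43437000, had a difference of 13.8 points, and the 1 cytosine called singly, on chromosome 11 at position 69753918, one of -17.6 points; both were named after their values were seen. Without each single library the number at an unadjusted p below 0.05 ranged from 5002 (without PML-RARα CD34− replicate 6) to 8459 (without PML-RARα CD34− replicate 14). In simulated data with 10 changed regions of each size 49.0% of true differences of 20 points were recovered, and 69.5% with 200 of each. Among cytosines whose group mean lay between 30 and 70%, the share that a library read as below 5% or above 95% was 8.44% ± 5.70 in PML-RARα and 1.61% ± 1.28 in WT CD34− libraries (SD, n = 5 each; two-sided exact permutation p = 0.0159, adjusted over 28 tests p = 0.148).

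The second pair of comparisons asks how methylation changes as promyelocytes mature from CD34+ to CD34−. In WT mice 382 regions on all 19 autosomes differed, of which 335 fell and 47 rose. The largest loss among them was on chromosome 9, positions 50701001 to 50702000, from 73.7% ± 10.2 to 5.64% ± 6.26 (adjusted p = 0.000146). Chromosome 15, positions 59538001 to 59539000, fell from 78.2% ± 12.1 to 21.4% ± 7.40, and chromosome 12, positions 82043001 to 82044000, from 57.0% ± 13.4 to 4.75% ± 4.18. Chromosome 5, positions 134691001 to 134692000, fell from 59.8% ± 11.2 to 9.31% ± 4.81. The largest gain among them was on chromosome 9, positions 116075001 to 116076000, from 18.2% ± 16.7 to 69.2% ± 4.48 (adjusted p = 0.00502). Chromosome 8, positions 12931001 to 12932000, rose from 30.9% ± 11.5 to 79.2% ± 5.02, chromosome 1, positions 64647001 to 64648000, from 54.1% ± 7.48 to 97.1% ± 3.02, and chromosome 4, positions 55754001 to 55755000, from 18.1% ± 10.3 to 58.3% ± 3.54. All values are means ± SD of 5 libraries. The 10 largest losses lay between -68.0 and -48.9 points and the 10 largest gains between 33.4 and 51.0 points. Of the 20 regions with the largest differences, 18 kept their call without each single library, 13 by limma and 13 by edgeR. The largest gain lost it without WT CD34+ replicate 9, and chromosome 19, positions 10103001 to 10104000 (68.2% ± 25.7 to 18.2% ± 12.7), without CD34− replicate 16 or 8 or CD34+ replicate 7.

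**Figure D1:**
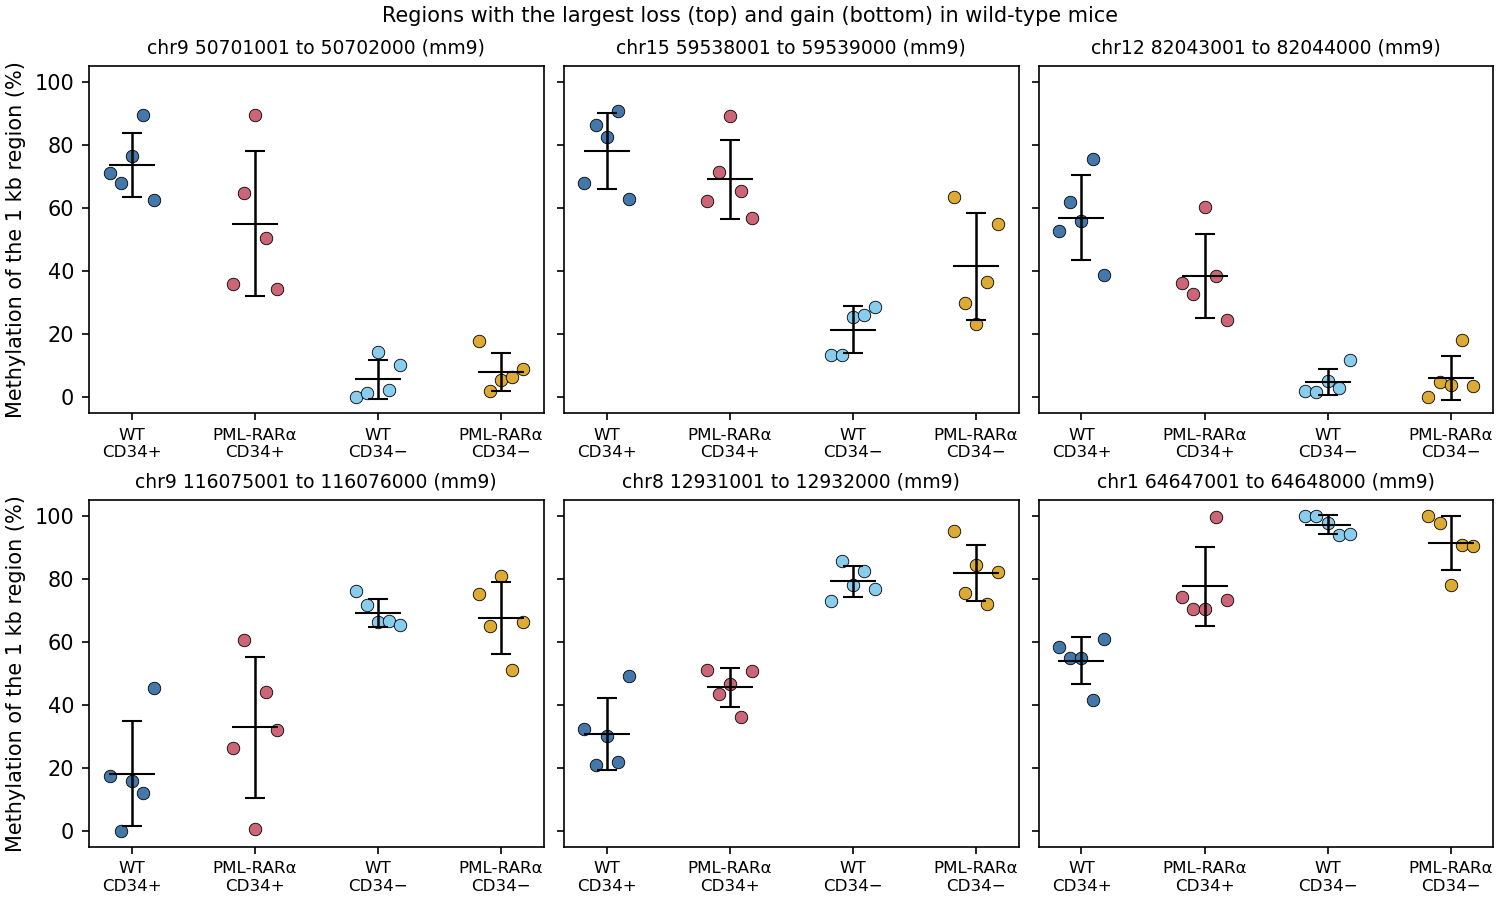
Methylation level (%) of 6 regions of 1 kb in each of the 20 libraries, by group, with the mean (long line) and SD (bars) of 5 libraries. The upper panels show the 3 called regions with the largest loss and the lower panels the 3 with the largest gain between CD34+ and CD34− cells of WT mice, such as the fall from 73.7% to 5.64% on chromosome 9, and in each panel the 5 CD34− WT libraries lie apart from the 5 CD34+ WT libraries.

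The median loss among the 335 regions was -25.5 points and the median gain among the 47 was 20.9 points. The median called region had a coverage of 518 per library, summed over its cytosines, so that a read over several cytosines counts once for each. Limma called 123 regions, edgeR 96, and a coverage minimum of 20 reads left 154, with 88.6%, 88.5% and 86.4% of them lower in CD34− cells. Without WT CD34+ replicate 9 the count was 217, and with flowcell as a factor it was 325.

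In PML-RARα mice 61 regions differed between the fractions, of which 52 fell and 9 rose. The largest loss among these called regions was on chromosome 1, positions 135000001 to 135001000, from 54.1% ± 19.7 to 11.2% ± 3.81 (SD, n = 5 each; adjusted p = 0.0211), where CD34+ replicate 11 stood at 87.9% and the other 4 between 37.3% and 51.3%. Chromosome 10, positions 67282001 to 67283000, fell from 64.9% ± 11.8 to 24.9% ± 16.7, chromosome 5, positions 134691001 to 134692000, from 41.7% ± 11.7 to 6.93% ± 3.63, and chromosome 13, positions 44504001 to 44505000, from 59.1% ± 5.18 to 25.8% ± 2.46 (adjusted p = 0.000385). The largest gain among them was on chromosome 4, positions 55754001 to 55755000, from 28.5% ± 13.0 to 68.1% ± 5.53 (adjusted p = 0.0171). Chromosome 8, positions 12931001 to 12932000, rose from 45.6% ± 6.17 to 81.9% ± 8.93, and chromosome 11, positions 100753001 to 100754000, from 24.3% ± 6.70 to 47.0% ± 10.1. The median loss was -19.8 points and the median gain 14.1 points.

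The PML-RARα count depended on the fit: it was 0 with flowcell as a factor, 13 by limma, 5 by edgeR, 13 at a coverage minimum of 20, 6 with only the 2 groups fitted, 38 after thinning, 37 for single cytosines and 18 without the 5 libraries of high scatter. In these mice flowcell and fraction overlap, so that the flowcell factor also takes up part of the difference between fractions. The test was lenient here in simulated data, where 7.34% of unchanged regions had an unadjusted p below 0.05, against 2.96% in WT mice. Of the 19 regions the naming rule gave, 2 kept their call without each single library, those that fell on chromosome 5, positions 134691001 to 134692000, and chromosome 13, positions 44504001 to 44505000. The other 17 lost it without at least 1, and 3 of the 19 kept it by limma and 1 by edgeR. The count was 13 without CD34+ replicate 19, 32 without CD34− replicate 20, 33 without CD34+ replicate 3 and 37 without CD34+ replicate 5.

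The 2 maturation comparisons shared 49 called regions, with 333 called in WT only and 12 in PML-RARα only. All 49 moved in the same direction. Fisher's exact test over regions, which are not independent replicates, expected 0.276 shared regions (p = 8.48e-105). It takes every region as equally callable in each comparison. Both comparisons used 1 overdispersion per region, shared by the 4 groups. Regions of 20 to 80% methylation, 17.4% of all, held 72.0% of the WT and 67.2% of the PML-RARα calls. The test therefore cannot say how far the overlap exceeds chance. Of the 382 WT regions, 374 (97.9%) had the same sign in PML-RARα mice, and of the 61 PML-RARα regions all 61 had the same sign in WT mice. The share with the same sign over all regions is not given here. The WT regions that fell had a median difference of -13.5 points in PML-RARα mice, against a median of -25.5 points in the WT libraries on which they were chosen. Chromosome 9, positions 50701001 to 50702000, for example, was 55.0% ± 23.0 in CD34+ and 8.10% ± 5.98 in CD34− cells of PML-RARα mice (SD, n = 5 each).

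Whether maturation differed between the genotypes was tested region by region as an interaction. The quasi-binomial test called 0 regions, with 4378 at an unadjusted p below 0.05, and the interaction was not run in limma or edgeR. With flowcell as a factor 2 regions were called, on chromosome 5, positions 142430001 to 142431000, and chromosome 9, positions 4896001 to 4897000 (adjusted p of 0.0145 and 0.0426, against 0.939 and 0.949 without it). These 2 were named after their values were seen. The different numbers of called regions do not by themselves show that the genotypes differ.

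**Figure D2:**
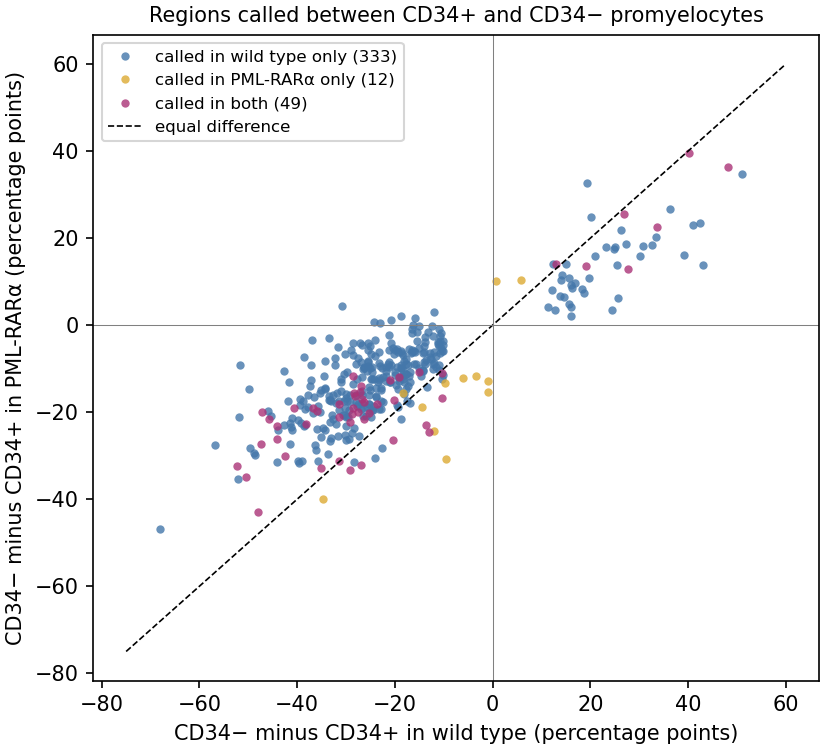
Difference between CD34− and CD34+ cells (percentage points) in WT mice (horizontal axis) and PML-RARα mice (vertical axis) for each region called in either genotype, with a dashed line where both are equal. Of the 382 regions called in WT mice 374 have the same sign on both axes, as do all 61 called in PML-RARα mice.

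Mean methylation over the shared cytosines fell with maturation in WT mice, from 29.9% ± 0.151 in CD34+ to 29.5% ± 0.153 in CD34− cells (SD, n = 5 each), a difference of -0.429 points (two-sided exact permutation p = 0.00794, the smallest these groups allow; adjusted p = 0.0317). Every CD34− library lay below every CD34+ library. Within flowcells the difference was -0.586 on A, -0.362 on B and -0.306 on D, with 2, 1 and 2 libraries per fraction. In PML-RARα mice the means were 29.7% ± 0.204 and 29.4% ± 0.142, a difference of -0.265 points (exact permutation p = 0.0556, adjusted p = 0.111) and of -0.345 within flowcell B, the only one with both fractions. PML-RARα differed from WT by -0.210 points in CD34+ cells (exact permutation p = 0.111, adjusted p = 0.148). The difference was -0.0723 on flowcell B (3 PML-RARα and 1 WT library) and -0.350 on D (1 and 2). In CD34− cells the difference was -0.0458 points (exact permutation p = 0.627, adjusted p = 0.627). It was -0.00391 on A (3 PML-RARα and 2 WT libraries) and -0.0549 on B (2 and 1). The adjusted p-values cover these 4 comparisons. When all reads were pooled, which weights cytosines by their coverage, or when each library kept every cytosine it listed, the WT maturation difference was -2.70 and -0.594 points and did not pass the test (exact permutation p = 0.206 and 0.460).

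**Figure D3:**
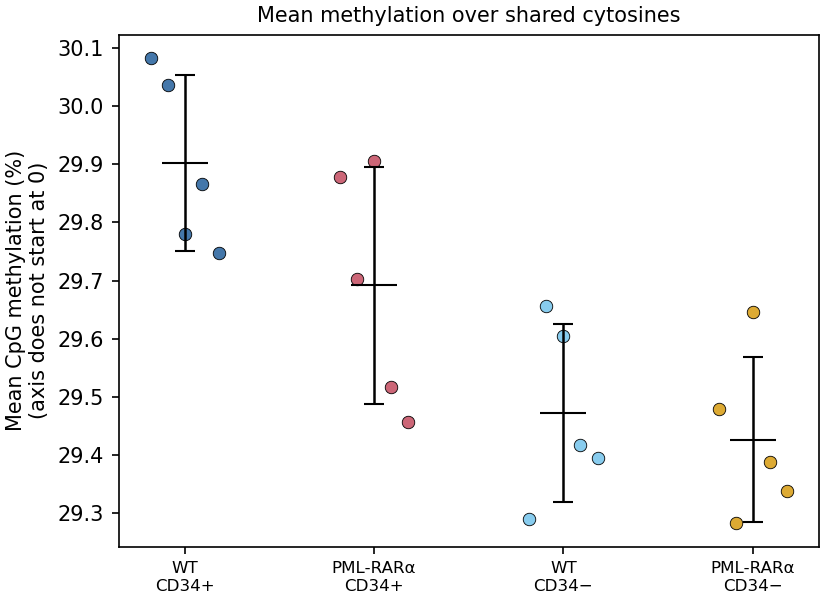
Mean CpG methylation (%) over the cytosines shared by all 20 libraries, one point per library, with the mean (long line) and SD (bars) of the 5 libraries of each group; the vertical axis does not start at 0. The WT groups average 29.9% in CD34+ and 29.5% in CD34− cells, without overlap, and the PML-RARα groups average 29.7% and 29.4%.

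Regions were also grouped by methylation level and by number of cytosines. In WT mice regions of 20 to 80% methylation averaged 58.5% ± 0.750 in CD34+ and 56.5% ± 0.809 in CD34− cells, a difference of -2.02 points, and regions above 80% differed by -0.939 points (exact permutation p = 0.00794 each, n = 5 each). Regions of 3 to 9 cytosines differed by -1.12 points with the same p. After adjustment over 24 exact permutation tests these 3 values had p = 0.0635, and no class passed in any comparison. Each of the 3 stood at the smallest p that 5 against 5 libraries allow. Alone, 3 values at that limit could not pass an adjustment over 24 tests, so that the adjusted p does not speak against these differences.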

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

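The measures of scatter and of strand correlation, the comparison of the libraries of high scatter with total coverage, their scatter at equal depth, that of the extra covariance between strands and the fit without these libraries were chosen only after the results were seen. In each group of 5 libraries a value was singled out when its gap to the nearest other value was large for the range of the group. The check was made in 154 groups and singled out 9 values, where chance gives about 1 in 20, or 7.7.

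WT CD34+ replicate 1 had a scatter of 7.82 points, against 3.52 to 4.40 in the other 4 libraries of its group. In the same library 23.8% of cytosines of intermediate methylation were read as below 5% or above 95%, against 0.658% to 2.53% in the others. PML-RARα CD34− replicate 12 had 0.207% of its mitochondrial reads methylated (95% Wilson interval 0.160% to 0.268%), against 0.0838% to 0.101% in the others of its group.

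At 6 of the regions named in the comparisons 1 library stood apart from the others of its group. PML-RARα CD34+ replicate 11 stood at 100% on chromosome 9, positions 61481001 to 61482000 (92.5% to 93.8% in the others). It stood at 90.1% on chromosome 18, positions 36651001 to 36652000 (77.8% to 79.2%), and at 87.9% on chromosome 1, positions 135000001 to 135001000 (37.3% to 51.3%). PML-RARα CD34+ replicate 19 stood at 5.60% on chromosome 12, positions 77568001 to 77569000 (0 to 1.51% in the others). WT CD34+ replicate 15 stood at 44.3% on chromosome 9, positions 61733001 to 61734000 (32.1% to 35.5%). PML-RARα CD34− replicate 4 stood at 18.1% on chromosome 12, positions 82043001 to 82044000 (0 to 4.74%).

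High scatter occurred in 5 libraries: WT CD34+ replicate 1, PML-RARα CD34+ replicates 5 and 11 and PML-RARα CD34− replicates 6 and 12. The extra covariance between the strands of a CpG was 12.4% of the extra covariance between neighbouring cytosines of 1 strand. A true methylation difference of the cells would be shared by both strands, so this speaks only against it as the whole cause. The strands shared little in the other libraries too (median covariance 16.9, against 88.2 between neighbours). Between strands the covariance was 37.2 to 49.7 in the libraries of high scatter except PML-RARα CD34− replicate 6 (10.8), and at most 25.5 in the others. A true difference as part of the cause therefore stays open. Of the 5 libraries, 4 had the 4 lowest total coverages of the 20 (83631324 to 131888291, against at least 152712753 in the others). Against shallow sequencing as the cause in the fifth, PML-RARα CD34− replicate 6, only 1 of the 20 libraries had a higher total coverage. Against shallow sequencing as the whole cause in the 4, their scatter was at least 6.95 points over 5 draws with all 20 libraries thinned to the same number of reads at each region, and at most 6.78 in the 15 others. The gap was narrow for PML-RARα CD34− replicate 12 (mean 7.05, against 7.88 to 8.73 in the other 3), and why low total coverage and scatter occur together stays open. Few starting molecules remain a candidate explanation: the median ratio of cross-strand to same-strand correlation was 0.240 in these libraries and 0.299 in the others, so that both kinds met the bound set in advance and the ratio decides nothing. Without the 5 libraries the counts of called regions were 2 and 0 between genotypes in CD34+ and CD34− cells, and 452 and 18 with maturation in WT and PML-RARα mice.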

How the results depend on the processing

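The fit without the 5 libraries of high scatter and the held-out changes of consecutive title numbers as pairs were the alternatives chosen after the data were seen. The cause of a change was not tested unless it is named. Between genotypes in CD34+ cells 4 regions were called with 4 of 5 libraries per group required, 2 after thinning, 1 as a single cytosine and 2 without the libraries of high scatter. In CD34− cells 1 region was called with 4 of 5 libraries, 1 as a single cytosine and 1 by limma. All other settings gave 0, as did leaving out each library (0 to 0) there and for the interaction, which gave 2 regions with flowcell as a factor.

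The WT maturation count was 197 at a minimum of 25 points, 154 at a coverage minimum of 20, which tests fewer regions, 123 by limma and 96 by edgeR. It ranged from 217 to 376 when each library was left out. Under the other settings it lay between 276 and 549, and at least 86.4% of the called regions were lower in CD34− cells in every setting that tests the 10-point minimum. The PML-RARα maturation count was 16 at 25 points, 13 at a coverage minimum of 20, 38 after thinning, 37 for single cytosines, 6 with only the 2 groups fitted, 18 without the libraries of high scatter, 0 with flowcell as a factor, 13 by limma and 5 by edgeR. It ranged from 13 to 88 when each library was left out. The number after # as a replicate block gave 369 and 54 regions in WT and PML-RARα mice, and consecutive title numbers as a replicate block gave 323 and 82, of which 272 and 34 were among the 382 and 61. The residual correlation of consecutive numbers had a median of 0.0719 against -0.00934 for other pairs. It was over 0.1 in 3 of the 10 pairs, and 11 of the 20 libraries correlated best with their consecutive number. The highest value was 0.221 in consecutive pairs and 0.175 in other pairs. In the titles each of the 10 consecutive pairs holds a CD34+ and a CD34− library of the same genotype with the same number after #. These points favour pairing without settling it, since the labels name no shared mouse and not every pair passed 0.1. The main tests did not treat the libraries as pairs and would ignore such a pairing. Consecutive numbers as a replicate block gave an exact permutation p = 0.0317 instead of 0.0575 for the held-out difference between the genotypes in maturation.

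The WT maturation difference in mean methylation was -2.70 points over pooled reads (exact permutation p = 0.206), -0.594 over every cytosine of each library (exact permutation p = 0.460), -0.586 within flowcell A, and -0.429 with consecutive numbers as pairs (exact p = 0.0625, the smallest 5 pairs allow). It ranged from -0.475 to -0.384 over single libraries left out. The PML-RARα difference was -0.276 at a coverage minimum of 20 (exact permutation p = 0.0476), -3.03 over pooled reads (exact permutation p = 0.317), -0.361 over every cytosine (exact permutation p = 0.524) and -0.265 with consecutive numbers as pairs (exact p = 0.0625, all 5 pairs lower in CD34− cells). It ranged from -0.324 to -0.211 over single libraries left out. The genotype difference was -0.479 over pooled reads and -0.992 over every cytosine in CD34+ cells (exact permutation p = 0.865 and 0.167), and -0.809 and -0.759 in CD34− cells (exact permutation p = 0.754 and 0.341). Over single libraries left out it ranged from -0.264 to -0.151 in CD34+ and from -0.101 to 0.000185 in CD34− cells, the last without WT replicate 18.

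Genotype differences of region classes that did not pass the test changed sign without 1 library. In CD34− cells they ranged from -0.434 to 0.0468 points in regions of 20 to 80% (above 0 without WT replicate 18, and 0.00824 without WT replicate 2), from -0.175 to 0.00895 above 80% (without PML-RARα replicate 14) and from -0.0414 to 0.00746 in regions of 30 or more cytosines (without WT replicate 2). In CD34+ cells of the last class they ranged from -0.0411 to 0.0229 (above 0 without PML-RARα replicate 19, WT replicate 1 or PML-RARα replicate 3). Promoter windows and gene lists were not run, for lack of an mm9 gene table.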

Other observations

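The held-out tests (after the counts of called regions but not their own values were seen), the comparisons of mitochondrial coverage, the splits by flowcell and by total coverage and the held-out comparisons without the libraries of high scatter and with consecutive title numbers as pairs were chosen only after the results were seen.

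Regions that lose methylation with maturation were examined in libraries that took no part in choosing them. In each of 40 rounds 1 library per group was set aside, regions lower in CD34− cells were called on the other 16 libraries of both genotypes together (between 224 and 428 regions), and the libraries set aside were scored by their mean distance from the mean of the 4 groups. The scores were 15.0 ± 5.27 points in WT CD34+, 4.60 ± 4.84 in PML-RARα CD34+, -8.93 ± 4.04 in WT CD34− and -9.94 ± 1.66 in PML-RARα CD34− libraries (SD, n = 5 each). PML-RARα CD34+ cells thus lay nearer to the mature state, by -10.4 points (exact permutation p = 0.0238, adjusted over 5 tests p = 0.0397). The difference was -10.4 within flowcell B (3 PML-RARα and 1 WT library) and -14.6 within flowcell D (1 and 2). The exact permutation p lay between 0.0159 and 0.0397 when each single library was dropped from this comparison of scores. Without the scores of the libraries of high scatter the difference was -11.2 (exact permutation p = 0.0571, n = 3 and 4). Each remaining PML-RARα score (at most 5.81) lay below each remaining WT score (at least 7.39). No assignment of these scores gives a lower difference, so that this p could not be smaller in this direction. The dropped libraries still took part in choosing the regions and in the group means for other libraries. In CD34− cells the difference was -1.01 points (exact permutation p = 0.603). As a hypothesis, CD34+ promyelocytes of PML-RARα mice may already have lost part of the methylation that WT cells lose later. A different share of maturing cells within the CD34+ gate was not tested and stays open.

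More regions were called with maturation in WT mice (382) than in PML-RARα mice (61). In libraries set aside the change was -23.9 points in WT and -14.5 in PML-RARα mice, 60.8% of the WT change (exact permutation p = 0.00794 each, the smallest possible; adjusted p = 0.0198). The changes differed by 9.37 points (p = 0.0575 over all 63504 permutations of genotype within fractions, adjusted p = 0.0718). With consecutive title numbers as pairs the same difference had an exact permutation p = 0.0317 over all permutations of genotype among the 10 pairs (adjusted p = 0.0397, and p between 0.00794 and 0.0397 without each single pair). If the numbers mark pairs, this speaks against greater scatter of the PML-RARα libraries (median SD of a region 6.52 against 6.03 points) as the whole cause and for a smaller change in PML-RARα mice. The labels do not say that they do, so the 2 explanations cannot be told apart here. Flowcell stays open as well: the change was -27.4, -27.3 and -18.7 points within flowcells A, B and D in WT mice (2, 1 and 2 libraries per fraction). In PML-RARα mice it was -14.997 within flowcell B (2 CD34− and 3 CD34+ libraries). Only B holds all 4 groups, and there each WT fraction rests on 1 library. The bound set in advance, a negative change within flowcells, bears on the change and not on the gap between genotypes. With flowcell as a factor the counts were 325 and 0. In PML-RARα mice A held CD34− libraries only, and C and D held CD34+ libraries only. The factor therefore also takes up part of the difference between their fractions. The 0 thus cannot be read as an effect of flowcell or of genotype.

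Coverage of 13 mitochondrial cytosines was taken per 1000000 of the coverage summed over the shared autosomal cytosines. It was 524 ± 150 in CD34+ and 329 ± 70.6 in CD34− libraries of WT mice, and 532 ± 119 and 274 ± 68.8 in those of PML-RARα mice (SD, n = 5 each). The exact permutation p was 0.0159 in WT and 0.00794 in PML-RARα mice, the latter the smallest these groups allow. Both were 0.148 after adjustment over 28 tests, which a single value at that limit could not pass. Against flowcell as the whole cause, the CD34+ mean was higher in 4 of 4 combinations of flowcell and genotype that hold both fractions. Among these, WT mice on flowcell B had 1 library per fraction. A difference between the cell fractions, such as their mitochondrial content, is a candidate explanation, although it did not pass the adjustment. Total coverage (exact permutation p = 0.484 in WT and 0.675 in PML-RARα mice between the fractions) and fragment selection stay open.

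Other splits of the 10 libraries of each comparison into groups of 5 were tested, 100 per comparison with the real one included. For the WT maturation count of 382, 1 split called as many, the real one, and the highest other called 1. Among the splits drawn this excludes chance at the level of 0.05. For the PML-RARα maturation count of 61, 3 splits called as many, a share under 0.05. That share does not settle that maturation gave the 61 calls, since other splits called more. The highest other called 184. That split parted replicates 3, 6, 14, 19 and 20, the 5 PML-RARα libraries of highest total coverage, from the other 5. Replicates 6, 14, 19 and 20 were also all the PML-RARα libraries on flowcells A and C, so that total coverage and flowcell nearly coincide in it. The third of the 3 splits called 147 and held replicate 4, of low total coverage, in place of replicate 6. It still held replicates 3, 14, 19 and 20 together, so that this swap excludes neither total coverage nor flowcell. Both splits point to a structure of these libraries apart from the fractions, and its cause stays open. The same split by total coverage of the WT libraries called 0 regions. A split of the PML-RARα libraries by flowcell (A or C against B or D) called 0 as well. It had 10189 regions at an unadjusted p below 0.05, against 9835 in the PML-RARα split by total coverage and 4478 in the flowcell split of the WT libraries. The 2 PML-RARα splits differ only in the place of replicate 3, so that the 0 calls do not exclude flowcell. For the genotype comparisons and the interaction, where 0 regions were called, every split calls as many by definition, so that the splits say nothing about chance (highest other 1 in CD34+ cells, 2 in CD34− cells and 1 for the interaction). Of the splits in CD34− cells, 15 gave as many regions at an unadjusted p below 0.05 as the real 6802, with a highest other of 8183, so that chance cannot be excluded.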
